A study of Bos taurus with 9 samples.

How the data were processed

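Single-cell RNA sequencing of lactating Holstein cows gave 1 library for each of 9 tissues, namely reticulum, omasum, abomasum, ileum, rectum, liver, salivary gland (parotid), mammary gland and blood. The deposited files held UMI counts per gene and barcode, which the authors had made with Cell Ranger 3.1.0 according to the submitters' processing notes. Per the file headers the count matrices came from version 3.1.0 in 8 libraries and 4.0.0 in blood. The genome build was not given in the sources used here. Whether the tissues came from the same cow was not stated either. Each file held 27270 genes, of which 7888 had no symbol, and 119 symbols stood on 2032 genes, and genes that share a symbol were left out of the gene lists.

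The files held 103707 barcodes, while the design text stated 88013 cells. Cells were kept here with at least 500 UMIs, at least 250 genes and at most 25% of UMIs from 13 mitochondrial genes, which left 77392. The share kept was 95.4% in reticulum, 81.4% in omasum, 29.6% in abomasum, 70.7% in ileum, 63.8% in rectum, 90.3% in liver, 60.8% in salivary gland, 95.2% in mammary gland and 98.8% in blood. The abomasum had a median mitochondrial share of 46.7%, so most of its barcodes were lost to that limit. Doublets were scored with the Scrublet method in scanpy, and the top-scoring 0.8% per 1000 barcodes were removed in each library.

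Each library was clustered on its own, without integration, from 2000 variable genes, 30 principal components, 20 neighbours and Leiden resolution 1.0. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9. Clusters of different libraries were matched by name only. The filters, settings, gene lists and comparisons were fixed before the data were examined, except where this text says otherwise.

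Clusters were named from marker lists of 38 types by a rule written in 4 versions after the names were seen. A class needed a score of at least 0.3, at least 3 markers detected at 10 CPM, and no more markers of another class than of its own among its 10 leading genes of at least 100 CPM. The second version came because clusters of 1 class shared leading genes and stayed unnamed. The third came because immunoglobulin and T cell receptor genes without a symbol led clusters, and the fourth because chief-like clusters of the abomasum and a blood cluster stayed unnamed. Clusters with few UMIs and no own marker leading also stayed unnamed. All names are written as X-like.

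UMIs were summed over the cells of a class and scaled to the total of the class (CPM) with exact 95% Poisson intervals, and shares of cells with exact Clopper-Pearson intervals. No test was made, since each tissue had 1 library and cells of 1 library are not replicates. A member of the 28 fixed gene lists was called higher or lower when its CPM ratio was at least 2 or at most 0.5 with at least 50 CPM in the higher group. In each list up to 4 genes with the largest ratio were named, and outside the lists and markers 8 genes each way from 100 CPM up. Across epithelia, up to 3 members per list and tissue were named that stood at least 2-fold above every other tissue. A count under 3 UMIs was set to 3 UMIs for a bound. List medians were placed among 10000 random lists of matched expression, as description only. Classes needed 100 cells to be compared, which left out the T or NK-like and myeloid cells of the abomasum.

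The calling procedure was tested on simulated data made from the sums. Of 100 genes set 3-fold apart, 100% were called in squamous cells and 99% in salivary T cells against blood, and none of those set 1.5-fold apart. Intervals covered the set ratio for 96.5% and 95.7% of genes. The genes had a mean of at least 50 CPM and were set on either side of the 2-fold line, so these calls check the calculation only. The simulated counts held counting error only, so differences between animals, dissociations or cell mixtures were not covered. Alternatives covered doublet removal, mitochondrial share, UMIs per cell, resolution, the scaling of CPM, the level for a call, and free RNA. Of the naming alternatives, 5 were added after the data were seen, as were the placing of unnamed clusters, single cell types and leaving out the liver. The sets of small-intestine and large-intestine genes were also chosen after the data were seen, from a wider group of regional genes whose values had been looked at. The fixed erythrocyte list entered no comparison, and gave 94.7 CPM in the blood library and between 0.874 and 7.58 CPM in the others.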

Results

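Single-cell transcriptomes were available from 9 tissues of lactating Holstein cows, with 1 library each for reticulum, omasum, abomasum, ileum, rectum, liver, salivary gland (parotid), mammary gland and blood. The reticulum and omasum are forestomach compartments lined by stratified squamous epithelium and bathed in fermenting feed, and the abomasum is the glandular, acid-secreting stomach. The 9 libraries held 103707 barcodes and 686115665 UMIs, from 15464052 UMIs in the salivary gland to 129531970 in the omasum. Median depth per barcode lay between 2562 UMIs in the abomasum and 9802 UMIs in the reticulum. Filters and doublet removal left between 2239 cells in the salivary gland and 13213 cells in the mammary gland. With 1 library per tissue, a difference between tissues could not be separated from a difference between animals, dissociations or runs, and the intervals given here cover counting error only.

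The first question was which cells each library held. Lymphocytes and other immune cells outnumbered everything else in 6 of the 9 libraries, and epithelium was the largest class only in the stomach compartments. T or NK-like cells formed the largest class in ileum, rectum, liver, mammary gland and blood, while macrophage-like cells dominated the salivary gland. In blood this rank depended on 1485 unnamed cells, which scored highest as granulocytes and would bring that class to 3541 cells against 2674 T or NK-like cells. Immune-like cells were 28.7% of kept cells in the reticulum (95% interval 27.7 to 29.8), 38.4% in the omasum (37.4 to 39.3) and 21.4% in the abomasum (20.2 to 22.7). In the library labelled ileum they were 61.3% (60.3 to 62.3), in the rectum 75.7% (74.6 to 76.8) and in the liver 89.1% (88.3 to 89.8). The salivary gland had 74.4% (72.5 to 76.2), the mammary gland 70.0% (69.2 to 70.8) and blood 81.7% (80.9 to 82.5). The share depended on the filter and naming settings, among them in the salivary gland, where it was 45.0% under the first version of the naming rule, in the omasum, where it was 57.0% with the mitochondrial limit at 10%, in the abomasum, where it was 34.4% with that limit and 11.6% with none, and in the reticulum, where it was 15.5% under that first version.

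Among the lymphocytes, T or NK-like cells ranged from 1.40% of the abomasum library, where there were only 60, to 69.6% of the rectum library. The abomasum held mostly antibody-secreting cells instead, with B or plasma-like cells at 19.6% and 625 of those 842 cells plasma-like. Gamma-delta T-like clusters were named in reticulum (762 cells), omasum (179), liver (578) and blood (236), and clusters named NK or cytotoxic-like in rectum (1224), salivary gland (67), mammary gland (3947) and blood (99). Myeloid-like cells made up 55.3% of the salivary gland, 33.9% of the liver and 12.4% of blood. In the forestomach they were all dendritic-like, with 160 cells in reticulum and 308 in omasum. In the liver 1398 were monocyte-like, 896 macrophage-like and 183 dendritic-like, and in the salivary gland 1192 were macrophage-like and 47 monocyte-like.

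Squamous-like cells made up 47.2% of the reticulum and 57.2% of the omasum. Gastric-like cells made up 74.4% of the abomasum, with 986 chief-like cells, which make lysozyme and pepsinogen, 1437 mucous-like and 775 parietal-like cells. The proton pump gene ATP4A stood at 244 CPM in 151 of the parietal-like cells but at 44.6 CPM in the other 624, which were led by PIGR, AGR2 and trefoil genes, so that name is doubtful for most of them. The columnar cells of the gut, goblet, absorptive and crypt-like, were 30.3% of the library labelled ileum and 20.6% of the rectum. Hepatocyte-like cells were only 2.12% of the liver (155 cells) and cholangiocyte-like cells 1.19%. Mammary epithelial-like cells were 9.06% of the mammary gland, with 413 secretory luminal-like, 759 hormone-sensing or progenitor luminal-like and 25 myoepithelial-like cells. The mammary gland also held 19.3% endothelial-like cells, 2356 of 2547 of them lymphatic, and 13.0% granulocyte-like cells, with 885 neutrophil-like and 836 mast or basophil-like cells, although 364 of the latter gave 0 UMIs of the mast-cell gene MS4A2. Unnamed clusters held 23.9% of the reticulum, 16.2% of blood, 8.40% of the salivary gland, 4.43% of the liver, 2.62% of the omasum and 0.916% of the rectum, and none of the other libraries. The leading genes of the 1770 unnamed reticulum cells were keratinocyte genes such as FABP4 or KRT6A beside S100A8 or S100A9, which the naming rule counted as myeloid or granulocyte markers.

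**Figure D1:**
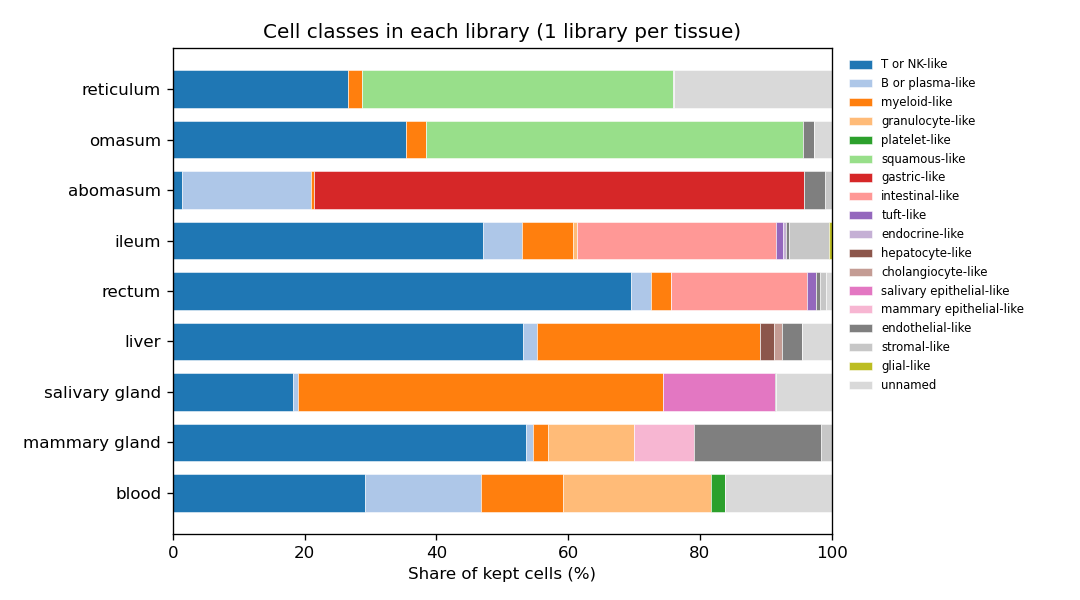
Share of kept cells (percent, horizontal axis) in each cell class for the 9 libraries, 1 bar per library and 1 colour per class. Immune-like classes together reach 89.1% in the liver and 21.4% in the abomasum.

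The second comparison asked how the squamous epithelium of the omasum differed from that of the reticulum. Both compartments absorb the acids of fermentation, and the omasum also takes up water and minerals from the outgoing feed. Their basal keratinocytes carried much the same absorptive and ketone-forming genes in the main grouping, which left out the unnamed reticulum clusters. The omasum had more of a chloride carrier and of several secreted or cytosolic proteins, and less of immediate early and heat shock genes. Of 185 list members measured, 10 were higher in the omasum, 10 lower and 165 in between. The omasum cells were 5691 basal-like and 225 suprabasal-like, and the 3503 reticulum cells all basal-like.

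None of the 11 transport genes for short-chain fatty acids and none of the 14 ketogenesis genes was called different. SLC16A1, the monocarboxylate carrier for acids and ketone bodies, stood at 429.6 CPM in the omasum and 422 CPM in the reticulum, and its chaperone BSG at 861 and 1208 CPM. BDH1, which makes hydroxybutyrate, reached 100.9 and 119 CPM, and the butyrate-oxidising ACADS 587 and 693 CPM. Some of these values depended on the cells kept, since with the mitochondrial limit at 10% the ratio was 0.478 for BDH1, and with at least 1000 UMIs per cell it was 0.499 for BSG. The desmosomal DSG3 and DSP and the tight-junction gene CLDN4 were also within 2-fold, and none of the 17 junction genes was called. S100A12, an antimicrobial calcium-binding protein, was abundant in both at 4296 and 4445 CPM in the main grouping. Its ratio was 0.414 with at least 1000 UMIs per cell, 0.476 with the unnamed clusters placed in their best-scoring class and 0.490 at resolution 2.

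Of the ion-transport genes with at least 50 CPM, the largest difference was in SLC12A2, the sodium-potassium-chloride cotransporter, at 98.3 CPM in the omasum and 2.23 CPM in the reticulum, a 44.0-fold difference (95% interval 36.1 to 54.4). AQP3, a channel for water, glycerol and urea, was 2.07-fold higher (2.01 to 2.13), a call that sat at the line and was 1.46-fold with at least 1000 UMIs per cell. ATP1B3, a sodium pump subunit, was 1780 against 1070 CPM, and the metal-binding MT2A 2462 against 1378 CPM. Outside the lists, CTXN3, a small membrane protein, stood at 186 CPM in the omasum and 1.66 CPM in the reticulum. CHI3L1, a secreted chitinase-like protein, was 16.3-fold higher, the cytosolic carbonic anhydrase CA3 9.51-fold and IGFBP3, which binds insulin-like growth factors, 3.42-fold, or 1.83-fold with the unnamed clusters placed in their best-scoring class. WFDC18, a secreted protease-inhibitor-like protein, was 3.56-fold higher in the main grouping but turned to a ratio of 0.710 with the unnamed clusters placed and 0.223 with at least 1000 UMIs.

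In the other direction, GLUL, which fixes ammonia into glutamine, was 23.5 CPM in the omasum and 81.6 CPM in the reticulum. The urea transporter SLC14A1, singled out after its values were seen and below the 50 CPM needed for a call, was 0.9203 CPM in the omasum and 30.8 CPM in the reticulum. RARRES2, which encodes the chemoattractant chemerin, was 5.30-fold lower in the omasum and the retinaldehyde-oxidising ALDH1A1 2.79-fold lower. IGFBP5 was 3.76-fold lower and the Notch target HES1 3.35-fold lower. S100A9 was 32.6 against 104 CPM, with a ratio of 0.574 as the mean of per-cell values. Immediate early and heat shock genes were lower for 8 of 15 members, including ATF3 at 127 against 565 CPM and FOS at 188 against 647 CPM, a ratio that was 0.598 with the mitochondrial limit at 10%. The median log2 ratio of that list was -1.10, below all 10000 matched random lists.

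Cell cycle genes were higher for 7 of 12 members, with the mitotic genes UBE2C at 105 against 6.24 CPM and TOP2A at 93.6 against 6.90 CPM. That result depended on an unnamed cycling cluster of 576 reticulum cells, in which UBE2C stood at 319 CPM. With the unnamed clusters placed in their best-scoring class, 1 list member in place of 10 was higher in the omasum, and at a finer clustering resolution the UBE2C ratio was 0.876 and the TOP2A ratio 0.595.

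The third comparison set the columnar epithelium of the rectum against that of the library labelled ileum. The ileum is known for absorbing bile acids and remaining nutrients, and the rectum for absorbing salt and water. Pooled over their types the columnar cells were much alike, and no list member of at least 50 CPM was 2-fold higher in the rectum. Immediate early genes were lower in the rectum, and antimicrobial genes lay mostly on the same side without any list member called. Of 188 members measured, 0 were higher, 13 lower and 175 in between. Goblet, absorptive and crypt-like cells numbered 1343, 841 and 760 in the library labelled ileum and 463, 471 and 278 in the rectum, and the types gave other counts than the pool. Between the goblet-like cells alone 12 members were higher in the rectum and 5 lower, and between the crypt-like cells alone 6 were higher and 23 lower. The types did not hold the same cells, since a cycling cluster of 158 cells counted as crypt-like in the library labelled ileum. A cycling cluster of 81 cells counted as goblet-like in the rectum. With the mitochondrial limit at 10%, 5 members were higher in the rectum and 7 lower.

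Several abundant salt and acid transport genes lay somewhat higher in the rectum pool without reaching 2-fold. SLC26A3, the chloride-bicarbonate exchanger of the large bowel, was 311 against 169.9 CPM and SLC16A1 422 against 295 CPM. ATP1B3 was 1357 against 833 CPM and the carbonic anhydrase CA2 2371 against 1645 CPM. Goblet-like and crypt-like cells, each taken alone, showed wider differences, with 2.79-fold and 2.42-fold for CA2, 2.34-fold and 2.22-fold for SLC16A1 and 2.31-fold and 2.40-fold for ATP1B3, and SLC26A3 was 2.26-fold higher between goblet-like cells. Nutrient genes included the fatty-acid binding FABP1 at 4255 and 3117 CPM (2.74-fold in goblet-like and in crypt-like cells alone), the gluconeogenic PCK1 at 337 and 394 CPM and the ammonia-fixing GLUL at 339 and 319 CPM. PIGR, which carries antibodies to the lumen, was 4974 and 5544 CPM.

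Outside the lists, PLAC8 was 2.31-fold higher in the rectum (2.22 to 2.39) but 1.12-fold between crypt-like cells, the ectonucleotidase ENTPD8 1.98-fold, CA7 1.74-fold (with a ratio of 0.439 between crypt-like cells), the lectin LGALS3 1.60-fold and LYPD8, a secreted protein that keeps flagellated bacteria off the mucosa, 1.60-fold. The 14 antimicrobial list members had a median log2 ratio of -0.60. None of them was called. Outside the list, genes lower in the rectum and picked for their ratios included MPTX, a pentraxin, at 128 against 375 CPM, BPI, which binds endotoxin, at 209.6 against 553 CPM, and the lysozyme LYSB, short of 2-fold, at 1004 against 1952 CPM. With the mitochondrial limit at 10% the ratio was 0.610 for MPTX and 0.618 for BPI, and LYSB was 0.184 between absorptive cells alone and 0.0240 between crypt-like cells alone. Lactoferrin, LTF, was 89.1 against 137 CPM. The MHC class II chain CD74 was 31.2 against 79.0 CPM, but T or NK-like cells of the rectum library carried 40.1 CPM, so the rectum value was no higher than in neighbouring cells, and the ratio was 0.727 with the mitochondrial limit at 10%.

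Immediate early and heat shock genes were lower in the rectum for 12 of 15 members, with EGR1 at 69.2 against 345 CPM and FOS at 34.4 against 122 CPM. ZFAND2A and PPP1R15A, induced by protein stress, were 5.23-fold and 2.81-fold lower. Most genes of the small intestine were low or absent in the library labelled ileum, by gene sets that were chosen after a wider group of regional genes had been looked at in these cells. Of 18 listed, 11 could be counted because another class in the series expressed them, and 1 of these, ANPEP, reached 10 CPM there at 63.2 CPM. SI lay just under that line at 8.45 CPM, and SLC5A1 was 4.80 CPM. The ileal bile-acid genes FABP6 and SLC10A2 gave 1 UMI and 0 UMIs, though FABP6 was not among the countable genes. Of 12 genes of the large intestine, 8 reached 10 CPM in the rectum. For these the line was set on the rectum value alone, and HOXA13 was 9.38 CPM in the library labelled ileum. In the library labelled ileum 6 of the 8 were within 2-fold, including the carbonic anhydrase CA1 at 755 and 924 CPM. All 8 were lower there than in the rectum, with ratios from 0.2296 for CA4 to 0.9255 and a median of 0.5868.

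The fourth comparison set the gastric epithelium of the abomasum against the squamous epithelium of each forestomach compartment. The abomasum secretes acid, lysozyme and pepsinogen, and does not face fermentation. Its cells carried less of the main monocarboxylate carrier, of several ketone-forming enzymes and of 4 of 17 junction genes, and a lysozyme load that took up a large part of all transcripts. Against the reticulum 8 members were higher and 36 lower of 191, and against the omasum 7 higher and 39 lower of 189. LYZ2 alone stood at 370393 CPM and LYZ3 at 64191 CPM, which lowers every other gastric value. With the most abundant genes left out of the total, each log2 ratio was higher by 1.07 against the reticulum and 1.13 against the omasum, and 34 and 29 members were then higher. With the mean of per-cell values 19 and 18 were higher and 27 and 27 lower, and with mucous-like cells alone 27 and 24 were higher and 25 and 20 lower.

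SLC16A1 was 10.5 CPM in the gastric cells against 422 CPM in the reticulum and 429.6 CPM in the omasum. BDH1 was 11.04 CPM against 119 and 100.9 CPM. In all, 6 of 14 ketogenesis genes were lower against each compartment. AQP3 was 15.0-fold lower than in the reticulum and 31.1-fold lower than in the omasum. The metal-binding MT2A stood at 13.4 CPM against 1378 and 2462 CPM. DSG3 gave 0 UMIs in the gastric cells, at least 3805-fold lower than in the reticulum and at least 5303-fold lower than in the omasum, and CLDN4 was 0.679 CPM. Of the squamous genes, KRT17 was 1606 and 3211 CPM in the forestomach and 0.0776 CPM in the abomasum, and the fatty-acid binding FABP4 gave 0 UMIs there.

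Among ion-transport genes the carbonic anhydrase CA2 stood at 503 CPM against 0.391 and 0.266 CPM in reticulum and omasum. The sodium pump subunit ATP1B1 was 8.47-fold and 10.3-fold higher, while ATP1B3 was 1.55 CPM against 1070 and 1780 CPM. GLUL was 2.07-fold and 7.18-fold higher, the first 1.67-fold with the mitochondrial limit at 10%. PIGR reached 422 CPM and gave 1 UMI in the reticulum and 0 in the omasum, while S100A12 was 0.349 CPM in the abomasum. Outside the lists the gastric cells carried ANXA10 at 424 CPM and the stomach claudin CLDN18 at 188 CPM, each with 0 UMIs in both forestomach epithelia. The tetraspanin TSPAN1 reached 307 CPM and GCNT3, which builds mucin glycans, 118 CPM. Immediate early genes were lower for 14 of 15 members against the reticulum and 11 against the omasum, but against the omasum the list median stood at percentile 39.9 of the matched random lists.

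The fifth question was which epithelium led in each nutrient or milk gene. Most members that set 1 epithelium apart were mammary milk genes, some of which had named those cells, and a gene shared by the gut pair or the forestomach pair could not lead. Of 168 members, 30 had at least 50 CPM in 1 epithelium and were there at least 2-fold above all others, 18 of them in the mammary gland, 7 in the salivary gland, 4 in the liver and 1, AQP3, in the omasum, a lead that was 1.46-fold with at least 1000 UMIs per cell, 1.62-fold at resolution 2 and below 2-fold under further settings. The liver entered with its hepatocyte-like cluster alone, without the 87 cholangiocyte-like cells, in which APOA1 stood at 28055 CPM and SLC5A1 at 65.4 CPM. The lists for ketogenesis, gluconeogenesis, bile acids and calcium, iron and zinc had no such member, while milk protein had 7, milk fat 8, lactose 3 and sodium, chloride and bicarbonate 5, the last all salivary. By that rule reticulum, abomasum, ileum and rectum led in no member. The hepatocyte-like cluster held only 155 cells and carried T cell transcripts, so a list without a liver lead says little about hepatocytes.

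The salivary epithelium entered with 380 cells, without 188 unnamed cells that carried BPIFB1 at 78881 CPM and LTF at 16569 CPM. In those 380 cells CA6, the secreted carbonic anhydrase of saliva, reached 3352 CPM. SLC26A6, an anion exchanger, was 214 CPM there and 5.61 CPM in the next tissue, the reticulum. The potassium channel KCNN4 was 8.72-fold above the rectum, ATP1B1 5.61-fold above the rectum and the glutamate carrier SLC1A1 5.37-fold above the mammary gland. In the mammary epithelium CD36, a fatty-acid receptor, was 132 CPM and next highest in the ileum library at 0.734 CPM. FABP3 was 7.85-fold above the rectum, XDH 3.05-fold above the salivary gland, APOE 2.66-fold above the hepatocyte-like cluster (1.67-fold with no mitochondrial limit) and the galactosyltransferase B4GALT1 2.84-fold above the ileum library. The casein gene CSN1S1 reached 148527 CPM and gave 0 UMIs in the epithelia of the other 7 tissues. In the liver the urea-cycle enzyme CPS1 was 70.7 CPM and APOC3 149 CPM. SLC2A3, at 671 CPM in the hepatocyte-like cells, was 759 CPM in T or NK-like cells of the same library. That cluster also held T cell transcripts, so its values, that of APOE included, are not those of hepatocytes alone.

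**Figure D2:**
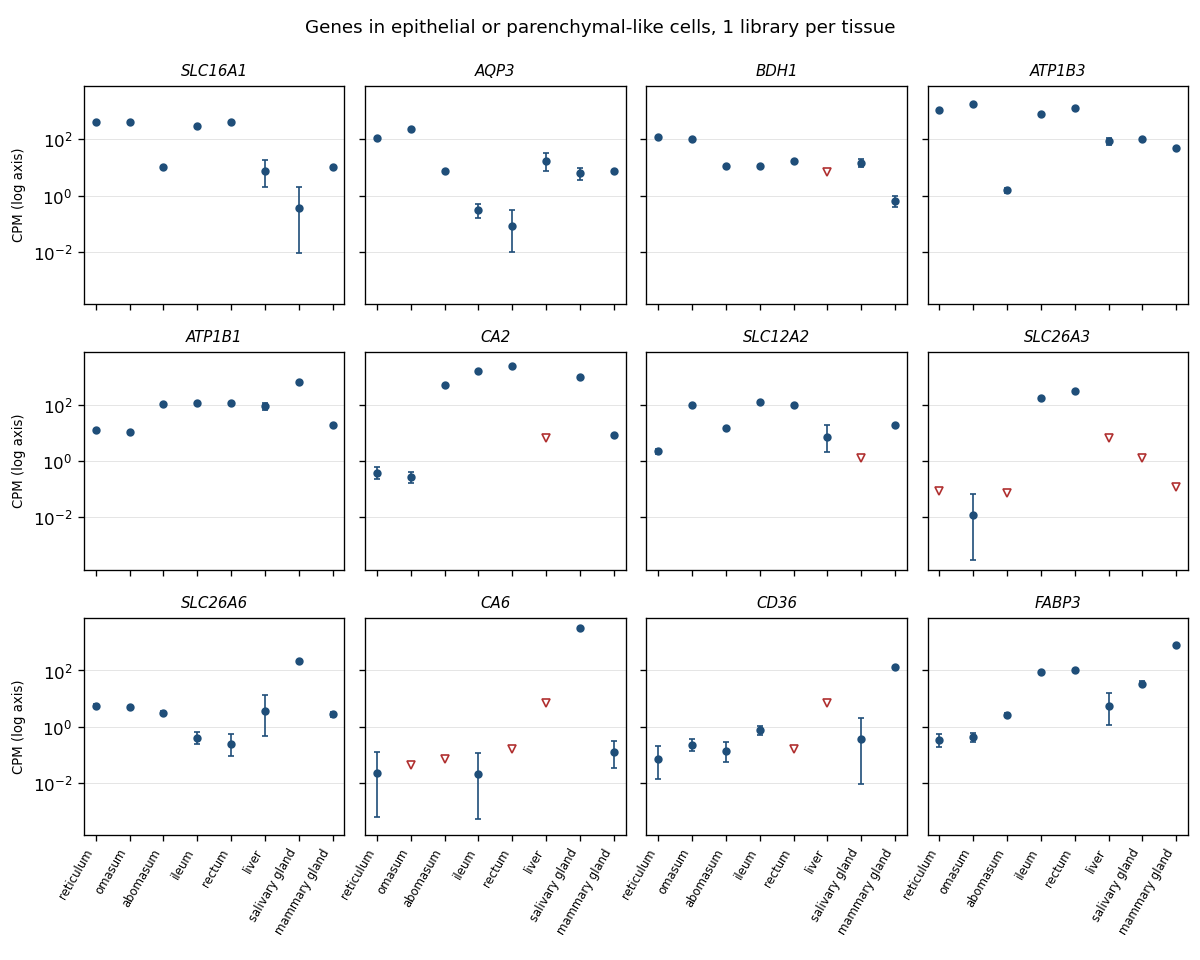
CPM (log axis) of 12 genes, picked after their values were seen, in the epithelial or parenchymal-like cells of the 8 solid tissues, 1 point per library with bars for 95% Poisson intervals, where open triangles mark 0 UMIs at the upper bound. SLC16A1 stands at 422 CPM in the reticulum and 10.5 CPM in the abomasum, and CA6 at 3352 CPM in the salivary gland.

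The sixth comparison asked which cells of the mammary gland carried milk genes. The 413 secretory luminal-like cells were set against the other 12800 cells of the library. Milk protein genes, BTN1A1, FASN and XDH were among the markers that named the secretory cells, so their high level there in part restates the name. Some other milk fat genes, among them CIDEA, SCD and FABP3, were also higher there, while LPL and CD36 were as high in another cell class. Of 33 members, 17 were higher in secretory cells, 2 lower and 14 in between. Milk protein genes took 76.1% of UMIs in secretory cells and between 0.929% and 3.57% in the other classes. Free RNA was not subtracted, so how much of the share in the other classes it made up is not known, and the folds depend on it.

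All 7 milk protein genes were higher, among them CSN1S1 at 241173 against 5555 CPM, CSN2 at 206997 against 4533 CPM and the whey protein gene PAEP at 152243 against 4115 CPM. Milk fat genes were higher for 9 of 19. BTN1A1, the butyrophilin of the fat globule membrane, was 51.6-fold higher (46.3 to 57.6), CIDEA, which merges lipid droplets, 26.3-fold and the lipoprotein lipase LPL 22.5-fold. FABP3 was 21.6-fold, the desaturase SCD 17.5-fold, FASN 4.50-fold, CD36 4.84-fold and XDH 2.23-fold higher. Single classes came close to or passed the secretory cells for LPL, at 176 CPM in stromal cells against 136 CPM, for CD36, at 211 CPM in myeloid cells against 166 CPM, and for XDH, at 379 CPM in endothelial and 465 CPM in stromal cells against 371 CPM. Of 8 lactose genes, LALBA and B4GALT1 were higher, the latter 2.02-fold but at 218 CPM in the other mammary epithelial cells, and HK1, a hexokinase, was 1.94 against 57.4 CPM. INSIG1, which restrains sterol-regulated transcription, was 60.3 against 306 CPM and SREBF1 16.6 against 17.8 CPM, ratios that were 0.822 and 3.88 with the most abundant genes left out of the total.

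Outside the lists the secretory cells carried CRISP3 at 641 CPM, HSTN at 2481 CPM, the fatty-acid transporter SLC27A6 at 135 CPM, the folate-binding FOLR3 at 128 CPM and the globule mucin MUC15 at 118 CPM, each over 30-fold above the other cells. The scaffold AKAP12 was 212-fold lower in them and IGFBP7 163-fold. AKAP12 was mainly endothelial, at 986 CPM, and IGFBP7 stromal and endothelial, at 983 and 810.3 CPM. With the most abundant genes left out of the total, each log2 ratio was higher by 2.06, and HK1 was then the only list member lower in secretory cells.

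The seventh comparison set T or NK-like cells of 7 solid tissues against those of blood. Their types differed, with 3947 NK or cytotoxic-like cells in the mammary gland and 1224 in the rectum against 99 in blood, and only T-like cells in the library labelled ileum. The labels gave an enzyme digestion of 20 minutes for liver and salivary gland, 30 for reticulum and omasum and 41 for rectum. No time was stated for ileum, mammary gland and blood, so tissue and dissociation could not be told apart. Lymphocytes of tissues are known to carry genes of residence and to lack the receptors that keep cells in circulation. Some genes of both kinds followed that split in all 7 tissues here, and on top of it the tissues differed. Of the 7, forestomach T cells carried the most IL17A, gut T cells the most CCL5, and mammary and liver T cells the most CTSW. Higher and lower members were 45 and 8 of 93 in reticulum, 33 and 12 of 92 in omasum, and 37 and 12 of 93 in the library labelled ileum. They were 28 and 12 of 90 in rectum, 34 and 8 of 94 in liver, 21 and 12 of 89 in salivary gland, and 37 and 7 of 94 in mammary gland. With the level for a call at 10 CPM, between 13 and 20 members were lower, and at 200 CPM between 2 and 5. Leaving the most abundant genes out of the total shifted the log2 ratios by -0.13 in the reticulum and 0.15 in the liver.

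A summary thought of after the data were seen counted members called the same way in all 7 tissues. Of 95 members, 10 were higher everywhere, namely JUN, CD69, DNAJB1, PRDM1, FOS, RGS1, ZFP36, CCL4, CXCR6 and HSPA1A. Another 5 were lower everywhere, among them S1PR1, LEF1, KLF3 and CCR7. RGS1, which dampens chemokine receptors and marks resident cells, ranged from 225 CPM in the salivary gland to 4452 CPM in the omasum, against 24.5 CPM in blood. The salivary value lay below the 1408 CPM of the myeloid cells around them. CXCR6 ranged from 172 CPM in the liver to 487 CPM in the reticulum against 51.3 CPM in blood. CD69, which retains cells by blocking S1PR1, was 1405 CPM in the liver and 659 CPM in the library labelled ileum against 45.4 CPM in blood. S1PR1, the exit receptor, was 0.0825 CPM in the rectum and 44.8 CPM in the liver, close to the line for a call, against 98.4 CPM. Its liver ratio was 0.504 by the mean of per-cell values and 0.505 without the most abundant genes, and the call was then lost. The naive-cell factor LEF1 lay between 3.91 and 23.1 CPM against 153 CPM. Of the 10 members higher everywhere, 5 belong to the immediate early and heat shock list, which was higher for 14 of 15 members in reticulum, 11 in omasum, 14 in the library labelled ileum, 10 in rectum, 15 in liver, 6 in salivary gland and 12 in mammary gland. With free RNA genes left out, 3 members were lower everywhere. That setting drops genes far below their level in the most abundant other class of the tissue library. A gene low in the tissue cells could thus be lost by the rule itself.

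The type 17 list was higher for 8 of 12 members in the reticulum, 4 in the omasum and 1 in the liver, and for none in the other 4 tissues. IL17A, a cytokine of barrier defence, was 2608 CPM in the reticulum and 1811 CPM in the omasum, but 27.6 CPM in the liver, 9.15 CPM in the library labelled ileum and 5.03 CPM in the rectum. Blood had 2 UMIs of it. The 60 T-like cells of the abomasum, too few to compare, carried 1128 CPM. IL17F was 2020 and 1787 CPM in reticulum and omasum and IL22, which acts on epithelium, 834 and 936 CPM. With 0 UMIs of both in blood, IL17F was at least 9970-fold and 8820-fold higher and IL22 at least 4117-fold and 4618-fold higher. The 2 groupings were unlike, since an unnamed omasum cluster of 271 cells, rich in these cytokines, was left out while a reticulum cluster with similar leading genes was kept. With that cluster added the omasum had IL17A at 2377 CPM, IL17F at 2515 CPM and 5 type 17 members higher. The checkpoint gene CTLA4 was 341 and 396 CPM against 9.46 CPM in blood, and IL10 was 146 CPM in the reticulum against 0.338 CPM. CGA, the glycoprotein hormone alpha chain, was an unlisted gene at 138 CPM in reticulum and 421 CPM in omasum against 0.338 CPM in blood. The cytotoxic genes CTSW and PRF1 were low in the omasum, at 14.0 and 5.12 CPM against 306 and 137 CPM in blood. Keratinocyte genes also appeared in these cells, KRT17 at 237 CPM in the reticulum where squamous cells had 1606 CPM, and S100A2 at 497 CPM in the omasum where squamous cells had 7222 CPM.

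Cytotoxic genes were higher for 6 of 11 members in the library labelled ileum and 5 in the rectum, as they were for 6 in the salivary gland, 6 in the mammary gland and 4 in the liver. CCL5, a chemokine of effector cells, was 7985 and 10835 CPM in the gut pair, 18.8-fold and 25.4-fold above blood. GZMA was 218 and 273 CPM against 25.8 CPM, and IKZF2 218 and 273 CPM against 29.5 CPM. The killer-lectin gene KLRJ1 was 357 and 697 CPM against 2.36 CPM, and TM4SF5 200.4 and 266 CPM against 11.4 CPM. Cell cycle genes were lower for 5 members in each of ileum, rectum and salivary libraries, with TOP2A in the gut pair at 1.80 and 0.9897 CPM against 62.8 CPM in blood. In the library labelled ileum that depended on the setting, since the TOP2A ratio was 0.922 with the mitochondrial limit at 10% and 0.670 with no doublets removed, and 7 members in place of 12 were then lower. IFNG was called higher in 6 of the 7 tissues, all but the salivary gland with 36.1 CPM, and ran from 82.6 CPM in the reticulum to 180 CPM in the liver, against 1.96 CPM in blood. CTSW, a protease of cytotoxic cells, was 1137 CPM in the liver and 1431 CPM in the mammary gland, 3.72-fold and 4.69-fold above blood, with 751 CPM in the salivary gland, 494 CPM in the rectum and 397 CPM in the library labelled ileum. The salivary gland stood out for GZMK at 205 CPM against 11.4 CPM. TNFRSF4, a costimulatory receptor, was lower in the gut, liver, salivary and mammary libraries, down to 3.84 CPM against 51.3 CPM in blood. Among unlisted genes lower in tissue, SCN2B and DAPL1 were at 104 and 110 CPM in blood and at 3.13 and 0.245 CPM in the mammary gland.

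**Figure D3:**
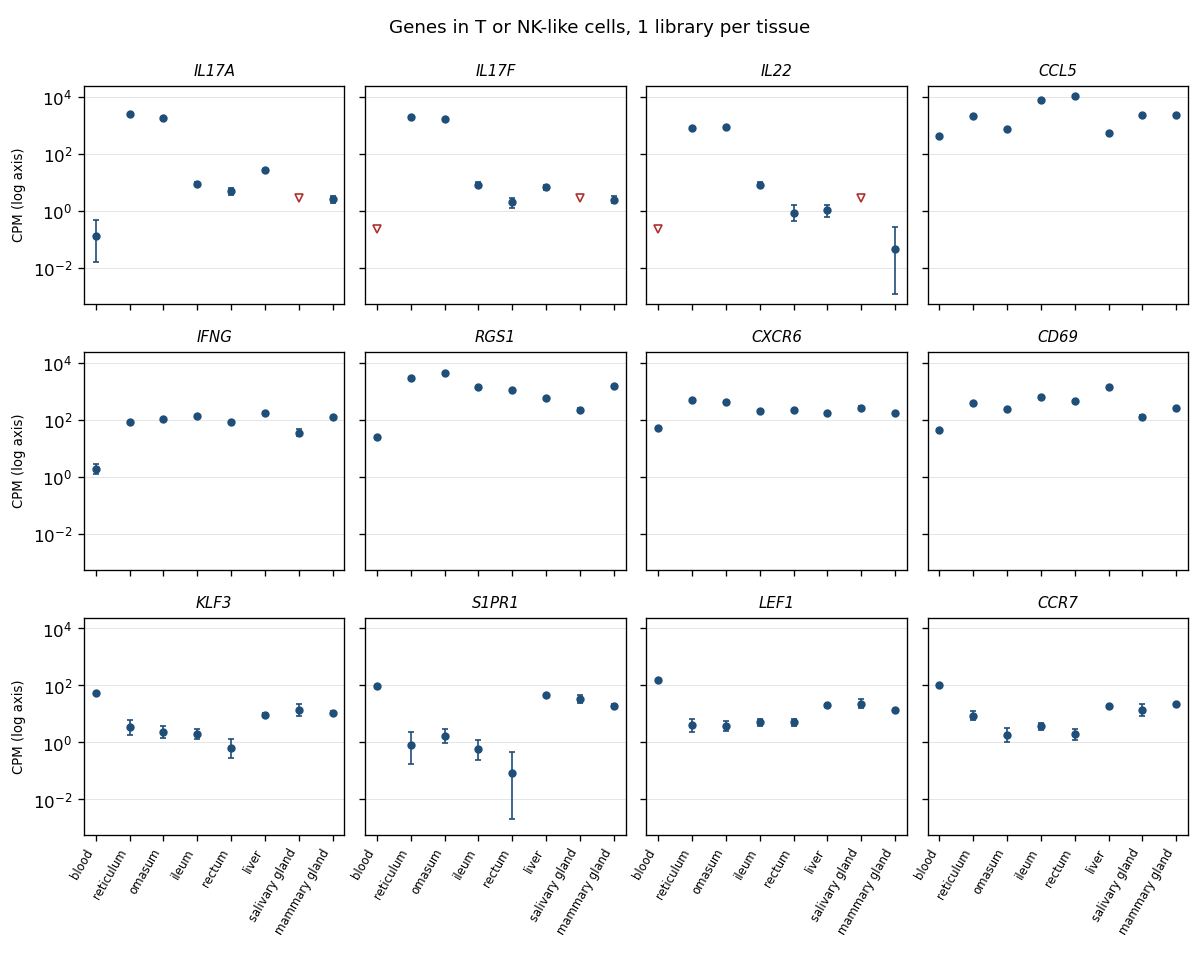
CPM (log axis) of 12 genes, picked after their values were seen, in T or NK-like cells of blood and 7 solid tissues, 1 point per library with bars for 95% Poisson intervals, where open triangles mark 0 UMIs at the upper bound. IL17A stands at 2608 CPM in the reticulum and 1811 CPM in the omasum, and LEF1 at 153 CPM in blood.

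The eighth comparison set myeloid-like cells of the same 7 tissues against those of blood. Blood monocytes are known to lose S100 proteins and gain scavenger and complement genes as they settle. The libraries fell into dendritic-like forestomach cells, macrophage-like cells of gut, salivary and mammary gland with APOE and TIMD4, and liver cells. In the liver cells most monocyte genes were not called different from blood, while 7 of 15 macrophage genes were called higher. The types compared were not the same, since blood held 977 monocyte-like, 122 macrophage-like and 34 dendritic-like cells, while the library labelled ileum held 520 macrophage-like and 233 dendritic-like cells, the rectum 116 and 65, and the mammary gland 203 and 94. Several members of the macrophage and monocyte lists, and of the cytotoxic list above, also served as markers for naming clusters, so their levels in part restate the names.

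Higher and lower counts came to 31 and 16 of 74 in reticulum, 32 and 12 of 74 in omasum, 26 and 15 of 74 in the library labelled ileum, and 28 and 15 of 74 in rectum. In liver they came to 28 and 1 of 76, in salivary gland to 30 and 12 of 74, and in mammary gland to 40 and 9 of 75. Of 76 members, 8 were higher in all 7 tissues, namely DNAJB1, HSPH1, PCNA, ATF3, FOSB, CCL3, CCL4 and HSPA1A. Of the 8, DNAJB1, HSPH1, ATF3, FOSB and HSPA1A belong to the immediate early and heat shock list, which was higher for 8 of 15 members in reticulum, 8 in omasum, 5 in the library labelled ileum, 5 in rectum, 12 in liver, 8 in salivary gland and 12 in mammary gland. As for the T or NK-like cells, tissue and dissociation could not be told apart. S100A12 alone was lower in all 7. No member stayed lower in all 7 with free RNA genes left out, 14 were higher in all 7 under the first version of the naming rule, and 3 with the mean of per-cell values. The free RNA setting can drop genes for being low in the tissue cells, so it cannot judge the lower calls. Leaving the most abundant genes out of the total shifted the log2 ratios by 0.13 in the rectum and -0.14 in the salivary gland.

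In the forestomach CD207, the langerin of epidermal dendritic cells, was 205 CPM in the reticulum and 316 CPM in the omasum, with 0 UMIs in blood. LTC4S, which makes leukotriene C4, was 925 and 804 CPM against 0.376 CPM. Cell cycle genes were higher for 10 and 11 of 12 members, against 6 in rectum, 2 in the library labelled ileum and 1 in each of liver, salivary and mammary gland, with BIRC5 at 275 and 109 CPM against 0.301 CPM. The invariant chain CD74 was 17868 CPM in the reticulum against 5024 CPM in blood. The monocyte gene VCAN was 2.23 and 2.62 CPM against 804 CPM, and the scavenger receptor CD163 2.98 and 4.12 CPM against 98.9 CPM.

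APOE, a lipid carrier of tissue macrophages, gave 0 UMIs in blood and 8244 CPM in the library labelled ileum, 7535 CPM in the rectum, 7190 CPM in the salivary gland and 5563 CPM in the mammary gland. TIMD4, which binds dying cells, was 506, 581, 379 and 199.7 CPM in the same order, with 1 UMI in blood. The folate receptor FOLR2 was 845, 552 and 586 CPM in ileum, rectum and salivary libraries against 10.0 CPM. CD74 was 8.12-fold, 6.69-fold and 5.25-fold higher in these. GPNMB, a lysosomal glycoprotein, was 1263 and 644 CPM in the gut libraries with 0 UMIs in blood, and CXCL9, a chemokine induced by interferon gamma, 802 and 454 CPM. CX3CR1, the fractalkine receptor, was 1476 CPM in the salivary gland, 12.7-fold above blood.

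Mammary myeloid cells had 13 of 14 inflammatory mediators higher. They included CCL4 at 4254 CPM against 2.48 CPM, the neutrophil chemokine CXCL8 at 2573 CPM against 3.99 CPM and the monocyte chemokine CCL2 at 1340 CPM against 0.978 CPM. Outside the lists CCL8 was 2560 CPM and the pentraxin PTX3 479.8 CPM in these cells. In liver myeloid cells 9 of 11 monocyte genes were not called, and only 1 list member was lower, S100A12 at 7794 CPM against 22358 CPM. The monocyte list still had a median log2 ratio of -0.67, at percentile 0.035 of the matched random lists. Of the 15 macrophage list members, 7 were higher. CD14 was 2.50-fold higher in the liver, and CD5L, a secreted protein of liver macrophages, was 173 CPM against 0.602 CPM. CXCL8 was 818 CPM and the cytokine OSM 413 CPM in the liver against 1.51 CPM of OSM in blood. The interferon-induced MX1 went the other way, at 27.7 CPM in the liver and 214 CPM in blood.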

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

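All tests below were chosen, and their predictions written, after the patterns were seen.

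The erythrocyte list entered no comparison, and the milk protein list outside the mammary gland at most that across epithelia. Both were counted over all barcodes of each library as a check, and counts above 3 UMIs were marked. Milk protein genes gave 7 UMIs in the reticulum, 65 in the library labelled ileum, 42 in the rectum and 161 in the salivary gland, against 16514278 UMIs in the mammary gland. CSN3 made up 60 of the 65, 33 of the 42 and 152 of the 161. Erythrocyte genes gave 204 UMIs in the reticulum, 158 in the omasum, 387 in the abomasum, 796 in the library labelled ileum, 229 in the rectum, 36 in the liver, 21 in the salivary gland, 183 in the mammary gland and 4689 in blood. The source of these counts was not tested.

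The columnar cells of the library labelled ileum carried large-intestine genes. Tissue of the large intestine under the ileum label could explain it, since 1 countable small-intestine gene reached 10 CPM there. In the rectum library 2 such genes reached 10 CPM, and a swap of the labels of ileum and rectum would need more there. Beyond their 95% intervals, 0 of the 11 countable small-intestine genes stood higher in the library labelled ileum than in the rectum. A mixture of ileal cells with cells of the large intestine would need some. Both counts argue against a swap or a mixture only if the bovine ileum expresses these genes. Countable meant only that another class in the series did. It stays open whether the bovine ileum itself differs from these gene sets, which were chosen after their values were seen.

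The hepatocyte-like cluster of the liver held T cell transcripts. Hepatocyte RNA carried by T cells could explain it, since T cell markers stood at a median of 0.902 of their level in T or NK-like cells. Intact hepatocytes with free T cell RNA were argued against by the same markers standing 17.7-fold above the myeloid cells of the library. Pairs of a hepatocyte and a T cell counted as 1 cell stay open, because the median of 3411 UMIs per cell was close to the 3707 of T or NK-like cells.

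Immediate early and heat shock genes were lower in rectum than in ileum epithelium and in omasum than in reticulum epithelium. A difference of the epithelium alone was argued against by T or NK-like cells, whose highest median log2 ratio over both pairs was -0.55. Of 15 members, 2 were called lower in these cells for rectum against ileum and 7 for omasum against reticulum. In the epithelium 12 and 8 were. A difference of the whole library could not be told apart, with 3 of 4 medians below 0 among T or NK-like and myeloid cells, and those of myeloid cells at 0.05 and -0.04. Dissociation was 30 minutes for reticulum and omasum, and 41 minutes for rectum, with none stated for ileum.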

How the results depend on the processing

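No paired analysis was possible because each tissue had 1 library and the labels pair none of them. The 5 naming alternatives, the placing of unnamed clusters, single cell types and leaving out the liver were chosen after the results were seen, and all other settings before.

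Of the main counts and shares under the alternatives, 697 stayed within the limits set, counted as kept, and 120 moved. Of all other values, mostly ratios of named genes, 2284 were kept, 846 moved and 14 reversed. The limits are not given here, and kept did not mean unchanged. Members lower in omasum squamous cells counted as kept at 15 with at least 1000 UMIs, against 10 in the main setting. The immune-like share of the reticulum counted as moved at 26.56% against 28.71%, with genes without a symbol among the leading genes. Where values moved, the cause was not tested, unless the setting itself changes which members can be called. Scores over the 9 libraries only, absorptive cells alone and leaving out the liver moved no main value.

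With no doublets removed the immune-like share was 23.84% in reticulum, 36.86% in omasum, 58.89% in ileum and 68.85% in mammary gland, and 7 members were lower in ileum T cells. With no mitochondrial limit it was 35.1% in omasum, 11.59% in abomasum, 55.91% in ileum, 70.22% in rectum, 82.83% in liver, 68.9% in salivary gland and 67.41% in mammary gland. With a limit of 10% it was 32.1%, 57.01%, 34.39%, 68.06%, 84.19%, 95.87%, 80.29% and 68.54% from reticulum to mammary gland, 1 member was higher in omasum squamous cells with a TOP2A ratio of 0.725, columnar cells had 5 higher and 7 lower, gastric cells 5 higher against the reticulum, and ileum T cells 7 lower. With at least 1000 UMIs it was 22.2% in reticulum, 76.95% in rectum and 93.54% in liver, 1 squamous and 1 columnar member were higher, and WFDC18 had a ratio of 0.2225.

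At resolution 0.5 the immune-like share of the omasum was 41.0%, 2 squamous members were higher, and the ratio was 0.7964 for TOP2A and 0.4693 for WFDC18. At resolution 2 the liver had 93.09%, 2 squamous members were higher, and the ratio was 0.8759 for UBE2C, 0.5951 for TOP2A and 0.2594 for WFDC18. With unnamed clusters in their best-scoring class the omasum had 40.99% and the liver 93.52%, 1 squamous member was higher, and TOP2A was 0.9513 and WFDC18 0.7096.

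With leading genes over all other clusters the salivary gland had 44.98%, 2 squamous members were higher with TOP2A at 0.8351 and WFDC18 at 0.4131, and 5 gastric members were higher against the reticulum. With genes without a symbol among the leading genes the reticulum had 26.56% and the omasum 35.39%, 6 squamous members were higher, WFDC18 was 0.2463, and 14 myeloid members were higher in all 7 tissues. Under the first version of the naming rule the share was 15.46% in reticulum, 33.17% in omasum, 81.18% in liver and 44.98% in salivary gland. That version also gave 2 squamous members higher with TOP2A at 0.706 and WFDC18 at 0.2129, 4 columnar members higher, 21 gastric members higher against the reticulum, 24 higher and 21 lower against the omasum, and 14 myeloid members higher in all 7 tissues. With markers detected at 50 CPM, gastric cells had 21 higher against the reticulum and 18 higher and 23 lower against the omasum.

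At a level of 10 CPM, which lets more members be called, squamous cells had 19 higher and 16 lower. Gastric cells had 26 and 57 against the reticulum and 21 and 59 against the omasum. T cells had 14 lower in reticulum, 20 in omasum, 19 in ileum, 20 in rectum, 13 in liver, 19 in salivary gland and 14 in mammary gland. Myeloid cells had 40 higher in ileum and 2 lower in liver, 17 T cell members were higher in every tissue, and 6 milk members were lower. At 200 CPM, which lets fewer be called, squamous cells had 1 higher, columnar cells 7 lower, and gastric cells 4 higher and 22 lower against the reticulum and 4 and 16 against the omasum. T cells had 3 lower in reticulum, 21 higher and 5 lower in omasum, 24 and 2 in ileum, 17 and 2 in rectum, 3 lower in liver, 11 and 2 in salivary gland and 23 and 2 in mammary gland. Myeloid cells had 20 higher in reticulum, 14 in omasum, 15 in ileum and 13 in rectum. In every tissue 3 T cell members were higher and 1 lower, and 1 myeloid member higher, and 1 milk member was lower.

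By the mean of per-cell CPM gastric cells had 19 and 18 members higher against reticulum and omasum, rectum myeloid cells 18 higher, liver myeloid cells 3 lower, and myeloid cells of every tissue 3 higher and 3 lower. Without mitochondrial, ribosomal and the most abundant genes gastric cells had 34 and 29 higher, reticulum T cells 15 lower, mammary T cells 12 lower, and 1 milk member was lower. Gastric mucous-like cells alone had 27 and 24 higher and 20 lower against the omasum. Goblet-like cells alone had 12 higher and 5 lower, and crypt-like cells 6 and 23. With free RNA genes left out 3 T cell members and 0 myeloid members were lower in every tissue. That setting can itself drop genes that are low in the tissue cells.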

Other observations

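All tests and clusters in this part were chosen after the data were seen.

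Some clusters outside the comparisons had distinct profiles. In the mammary gland a cluster of 364 cells carried IL13 at 629 CPM against 1.096 CPM in the rest of the library, CHGA at 570 against 0.480 CPM, the alarmin receptor IL1RL1 at 296 CPM and GATA3 at 604 CPM. It had little CD3E, at 69.3 against 279 CPM, and, although named mast or basophil-like, no UMIs of the mast-cell gene MS4A2 and CPA3 at 80.4 CPM, where another cluster of 472 cells had CPA3 at 1977 CPM and LTC4S at 2203 CPM. Tuft-like cells stood apart in both gut libraries, 106 in the library labelled ileum and 84 in the rectum. They carried LTC4S at 3851 and 3291 CPM, ALOX5 at 940 and 771 CPM, BPIFA2C at 1086 and 1116 CPM and the receptor IL17RB at 121 and 92.4 CPM, while the cytokine IL25 gave 1 and 0 UMIs.

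Among unnamed clusters, 502 blood cells carried the interferon-induced ISG15 at 18254 CPM and IFIT2 at 19447 CPM, and 983 blood cells the platelet and microglia receptor P2RY12 at 3128 CPM beside the neutrophil genes CSF3R at 3087 against 341 CPM in the rest and CXCR2 at 211 against 5.84 CPM. In the omasum 271 cells carried IL17A at 8850 CPM, IL17F at 10839 CPM, IL22 at 2359 CPM, the chemokine CCL20 at 1690 CPM and CD3E at 1231 CPM. They led with T cell genes but stayed unnamed because of markers shared with myeloid cells, and so stood outside the comparison with blood. In the salivary gland 188 cells carried BPIFB1 at 78881 CPM, lactoferrin LTF at 16569 CPM and complement C3 at 7972 CPM. In the reticulum 108 unnamed cells carried KRT6A at 4391 CPM, BPIFA2C at 2341 CPM and S100A8 at 10419 CPM.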
